A study of Arabidopsis thaliana with 6 samples.

How the data were processed

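Transcript levels were measured in the aerial part of 30-day-old Arabidopsis thaliana plants of the Col-0 wild type (3 arrays) and of the epiF3 line (3 arrays), each array holding biotin-labelled RNA of 1 sample on an Affymetrix expression array. Titles call the samples biological replicates 1 to 3 of each group, and the labels' protocols state that RNA was taken from each plant with TRIzol and purified on columns. Groups were taken from titles and source names, which call the second group epiF3. The description field of the same samples calls them albino plants of an msh1 mutant, and the labels do not settle how these names relate, so the group is called epiF3 throughout.

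The authors deposited 1 log2 value per probe set and array, and the submitters' processing notes name RMA (robust multi-array averaging) and the affy package, without versions. The scale was taken as log2 because values lie between about 1 and 13 on every array. Background method and probe set definition are not given in the sources used here. Low values pile up near 2 with exact ties, and no detection calls were used, so a change toward that floor is understated in size. Array medians of the probe sets tested lay between 4.08 on epiF3 replicate 3 and 4.32 on wild type replicate 2. The number of arrays limits the precision.

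The table holds 22810 probe sets, of which 64 are array controls and 22746 were tested. The platform annotation used here lists 14016 of them. It gives 1 gene for 13513 probe sets and several genes for 503, and 8730 are unnamed here. Of the 13513, 13436 were matched to a RefSeq gene table of the assembly TAIR10.1, which served for symbols and for the order of neighbouring genes only, and 77 were not. Most probe sets with 1 gene (11933) carry the locus name alone. For 147 genes with more than 1 probe set, the brightest stood for the gene in gene lists.

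The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, epiF3 minus wild type, two-sided, no block), with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05. No filter on dim probe sets was used. Arrays were simulated with 200 changed probe sets in each of 10 runs over 22746 probe sets. The test recovered 45.8% of 2-fold and 84.3% of 4-fold changes, and 3.8% of its calls were false. There the noise of each probe set had its moderated variance in this comparison, multiplied by a random factor from an F distribution. These shares are thus not the recovery of the real fit. In 20 simulated runs without any change, which used the moderated variance without that factor, the most calls in a run was 2. All simulated noise was drawn separately for each probe set, without deviations shared across an array.

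Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule takes the 12 largest rises and 12 largest falls among probe sets past the threshold that name 1 gene and whose arrays do not overlap between groups. It adds, for each list, up to 2 members that rose and 2 that fell, or the member with the smallest p where none passed. Lists with at least 5 measured genes (6 of 33) were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. Members of every list with more than 1 measured gene were also adjusted over the list alone. Organelle genes were taken by their RefSeq chromosome, since the planned match by locus name could not be applied. Only 81 of 585 nuclear list entries were measured under a name, and 6 lists had no measured member. The annotation used here names no probe set for MSH1, so that gene is not analysed here. A planned check of clock phase needs morning and evening genes, of which GI alone was measured, and was not made.

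Alternatives were median centring, cyclic loess and quantile normalization of the deposited values, filters on the dimmest 40% of probe sets and on those that can cross-hybridise, trended, robust and absent moderation, array weights, the replicate number as a block, a threshold of 0.01, a minimum of 2-fold, and leaving out each array. A covariate for the level of hybridization controls, a fit without genes in a chromosome block rich in calls, gene families by symbol and all analyses of gene order were chosen after seeing the data. Gene order was analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with 10000 shuffles of the calls among genes in 10 strata of mean expression. Figures were drawn with matplotlib 3.10.9. Dates and batches are not given in the sources used here.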

Results

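The series set the aerial parts of epiF3 plants against those of Col-0 wild type, with 3 arrays in each group and 22746 probe sets tested. The labels state only that the transcript profile of epiF3 plants was to be obtained, and the comparison asks which transcripts differ in level between the groups. Pearson correlations across probe sets, which are not independent replicates, were 0.994 between epiF3 replicates 1 and 2 and 0.981 to 0.989 among wild-type arrays. They were 0.961 to 0.982 between epiF3 replicate 3 and each other array, and 0.9735 to 0.9869 between epiF3 replicates 1 and 2 and the wild-type arrays. Wild type replicate 3 was closer to epiF3 replicates 1 and 2 (0.9869 and 0.9840) than to wild type replicates 1 and 2 (0.9835 and 0.9809). MSH1, the MutS homologue named in the description of the epiF3 samples, is not analysed here, so the labels could not be checked by that gene.

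Array signals of a small set of genes fell strongly in epiF3 plants. AT3G47250, which encodes a DUF247 protein, fell from 7.74 ± 0.03 in wild type to 1.93 ± 0.21 in epiF3 on the log2 scale (SD, n = 3 each), a limma change of -5.81 with a standard error of 0.14 and an adjusted p of 4.49e-06. AT3G43740, a leucine-rich repeat protein gene, fell by 4.45, and AT3G44630, a TIR-NBS-LRR disease resistance gene, fell by 3.86. Transcripts of QQS, an orphan gene known to affect starch content, were at 5.78 ± 1.1 in wild type and at 2.29 ± 0.13 in epiF3, and HTB11, a histone H2B gene, fell by 2.66. The largest named rise was that of AT1G10585, a bHLH transcription factor gene, from 2.86 ± 0.63 to 6.66 ± 0.75.

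The remaining genes of the 12 largest named falls were AT1G76960 (-5.29), AT1G73490 (-4.56), AT1G23960 (-4.21), AT1G12400 (-3.0), AT1G22890 (-2.97), the purple acid phosphatase gene AT1G13750 (-2.53) and the ceramidase gene AT5G58980 (-2.41). For AT3G47250 and AT3G43740 all 3 epiF3 arrays lay in the lowest 25% of values of their array, near the floor, so these changes are lower limits in size. After AT1G10585, the largest named rises were those of AT1G12080 (2.29), AT1G22550 (2.02), AT3G46490 (1.89), AT5G06570 (1.83), AT4G02360 (1.81), AT1G20490 (1.75), AT2G37900 (1.75), AT3G16330 (1.70), AT3G60980 (1.69), AT1G23850 (1.63) and AT4G30450 (1.57). AT1G22550 and AT2G37900 belong to the nitrate and peptide transporter family. Among these 24 genes and EXPA8, 9 kept their call under every alternative other than absent moderation. They were AT1G12080 among the rises, and AT3G47250, AT1G76960, AT1G73490, AT3G43740, AT1G23960, AT3G44630, AT1G12400 and HTB11 among the falls. The calls of QQS and AT1G10585 were lost without epiF3 replicate 2 and without epiF3 replicate 3, among other settings.

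**Figure D1:**
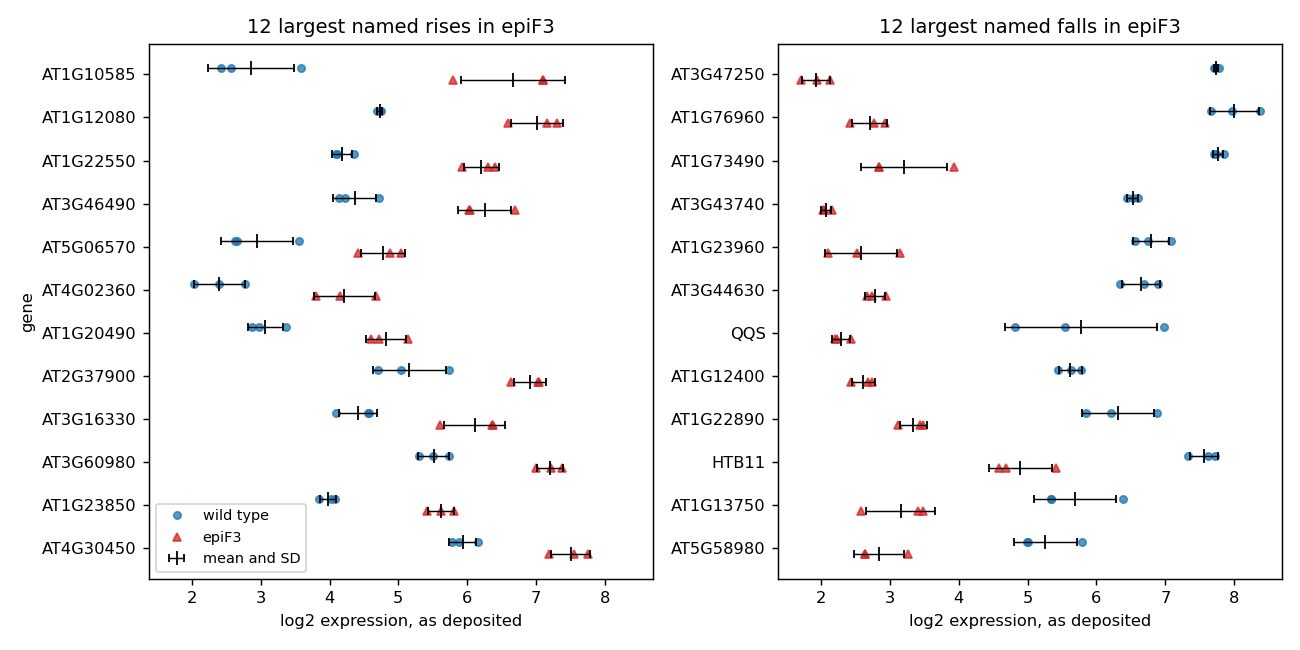
Log2 expression of the 12 largest named rises (left) and 12 largest named falls (right), with 1 point per array (blue circles, 3 wild-type arrays; red triangles, 3 epiF3 arrays) and bars for the mean and SD. The arrays of the groups do not overlap for any of these genes, and AT3G47250 lies at 7.74 in wild type and 1.93 in epiF3.

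In all, 61 probe sets were higher and 75 lower in epiF3 at an adjusted p under 0.05 in limma, and 52 and 68 of them changed by at least 2-fold. The 136 calls comprise 70 probe sets that name 1 gene, 7 that name several and 59 that are unnamed here, among them the largest rise of all (5.14). All 136 had arrays that did not overlap between the groups, as did 16.9% of all probe sets, against 10% by chance. The number of calls changed when single arrays were left out. It was 64 without wild type replicate 1, 54 without wild type replicate 2 and 402 without wild type replicate 3. It was 83 without epiF3 replicate 1, 33 without epiF3 replicate 2 and 62 without epiF3 replicate 3. All 136 kept their direction in each of these fits, which share most of their arrays. Leaving out an array also lowers precision. With the level of hybridization controls as a covariate, chosen after seeing the data, 6 probe sets were higher and 18 lower. That covariate partly overlaps with the group, so calls can be lost with it through lower precision alone.

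**Figure D2:**
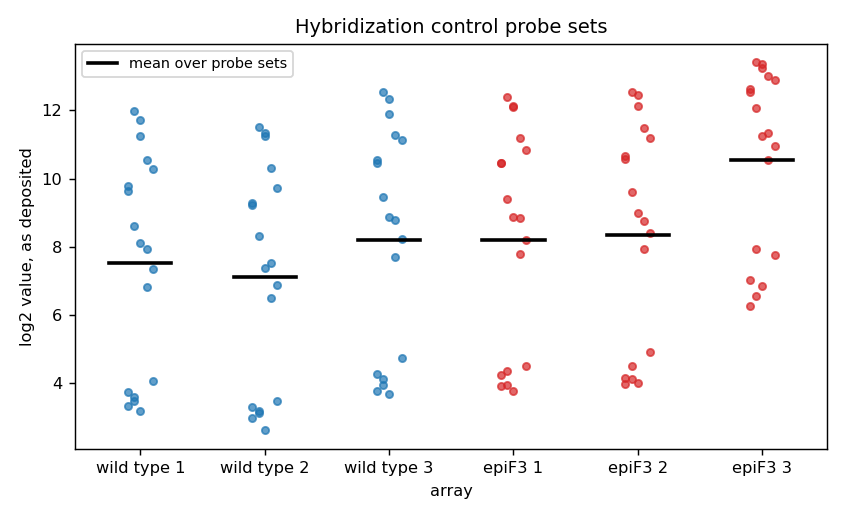
Log2 values of the 18 hybridization control probe sets on each array (points; blue, wild type; red, epiF3), with black lines for the mean over probe sets. The mean is 10.5 on epiF3 replicate 3 and between 7.11 and 8.36 on the other 5 arrays.

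Hybridization controls, bacterial and phage transcripts added as a reference, averaged 9.02 ± 1.31 in epiF3 and 7.62 ± 0.56 in wild type (SD, n = 3 each; two-sided exact permutation p = 0.2, with 0.1 the smallest possible). Differences between 3' and 5' probe sets of actin, GAPDH and ubiquitin, a measure of RNA integrity, gave exact permutation p of 0.6 to 1.0 between groups.

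Whether genes of chlorophyll synthesis were lower as a group in epiF3 was not settled. All 6 measured genes had negative changes, with a median of -0.33 (camera adjusted p = 0.00314 at the preset correlation). The estimated correlation was 0.579, and the adjusted p was 0.873 with it in camera and 0.392 in fry. Without wild type replicate 2 the median was -0.219 (camera adjusted p = 0.0201 at the preset correlation). PORB, a protochlorophyllide oxidoreductase, had a change of -0.92 with a standard error of 0.33, CHLI2, a subunit of magnesium chelatase, one of -0.62 with a standard error of 0.21, and GSA1, an enzyme of aminolevulinate synthesis, one of -0.46 with a standard error of 0.19. None of the 6 passed the limma threshold, over all probe sets or adjusted over the list alone. The hybridization controls averaged 9.02 in epiF3 and 7.62 in wild type, a difference not shown by test (exact permutation p = 0.2). With their level as a covariate the list's median was -0.14 (camera adjusted p = 0.373). The covariate partly overlaps with the group, so this loss cannot be told from lower precision.

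A group fall was not settled for genes of the plastid genome either. Of 69 measured genes, 44 had negative changes. The median was -0.093, or -0.021 after median centring (camera adjusted p = 0.0439 and 0.0217 at the preset correlation). The estimated correlation was 0.183, and the adjusted p was 0.873 with it in camera and 0.879 in fry. No plastid gene passed the limma threshold, and values ranged from -1.68 for atpA to 0.83 for psbD. psbC, the member with the smallest p, had a change of 0.61 and an adjusted p of 0.091. The list's call was lost under cyclic loess (adjusted p = 0.189), without wild type replicate 2 (0.974), without epiF3 replicate 2 (0.0935) and without epiF3 replicate 3 (0.267), and its median was 0.018 with the hybridization control level as a covariate.

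Nuclear genes of the light reactions were not shown to differ as a group (7 genes, 6 negative, median -0.065, camera adjusted p = 0.304). Their median was 0.007 after median centring, 0.009 after quantile normalization, and between -0.197 without wild type replicate 1 and -0.025 without epiF3 replicate 3 with 1 array left out. LHCB4.1, an antenna protein of photosystem II, had a change of -0.26. The 16 measured mitochondrial genes had a median of -0.019, or 0.052 after median centring, a mean of 0.0076 and a camera adjusted p of 0.832, with fry and camera opposite in sign, and cox1 had a change of 0.55. The mitochondrial median was -0.081 without wild type replicate 3 and 0.024 without epiF3 replicate 1. The 5 measured auxin genes had a median of 0.12, a mean of -0.072 and a camera adjusted p of 0.832, and IAA29 had a change of -0.45. The auxin median had no settled sign, at -0.109 without the dimmest 40% of probe sets, -0.002 without epiF3 replicate 3 and -0.089 with the hybridization control covariate.

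EXPA8, an expansin that loosens cell walls, fell by 2.23 (adjusted p = 0.0384 in limma), the only member of any fixed list past the threshold over all probe sets. EXPA8 lost that call under 7 of 17 alternatives, among them leaving out wild type replicate 2 or any single epiF3 array. The cell wall expansion list held 13 measured genes, 7 of them positive, with a median of 0.24, a mean of -0.037 and a camera adjusted p of 0.832. Its median was 0.068 without wild type replicate 2, 0.127 without wild type replicate 3 and 0.139 without epiF3 replicate 2. The fry p for change in either direction was 0.00221. Adjusted over the list alone, EXPA8 fell and EXLA2, an expansin-like gene, rose (0.80, with an adjusted p of 0.11 over all probe sets in limma).

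**Figure D3:**
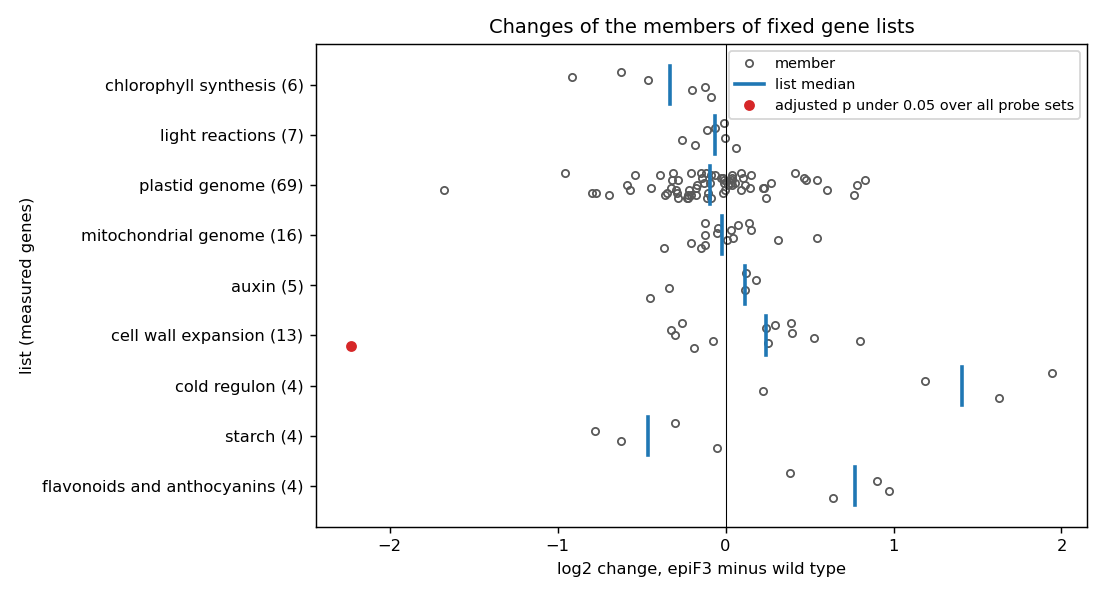
Log2 changes, epiF3 minus wild type, of the measured members of 9 fixed lists (open circles; filled red, adjusted p under 0.05 over all probe sets), with a blue line for each list's median and the number of measured genes in brackets. All 6 chlorophyll synthesis genes lie below 0, and EXPA8 at -2.23 is the filled point.

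The other 21 lists had 1 to 4 measured genes and no member past the threshold over all probe sets. Adjusted over the list alone, 3 of 4 cold regulon genes rose, namely the cold-regulated protein genes COR15A (1.95), LTI30 (1.63) and COR47 (1.19), whose adjusted p over all probe sets were 0.219, 0.13 and 0.218 in limma. In the jasmonate list, JMT, which methylates jasmonic acid, rose by that adjustment (1.96, adjusted p 0.126 over all probe sets). In the senescence list, WRKY53, a transcription factor of defence and senescence, fell by it (-2.93, adjusted p 0.194 over all probe sets in limma), with a wild-type SD of 1.84. In the starch list, PWD (-0.78) and DPE1 (-0.62), both enzymes of starch breakdown, fell by it, and all 4 members were negative. In lists with 1 measured gene no adjustment applies, and the unadjusted limma p was 0.037 for AGL24 of flowering time (0.60), 0.0139 for UGT74B1 of indole glucosinolates (0.41) and 0.00611 for WRKY53, also the 1 measured gene of pattern-triggered defence.

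No member passed in the other small lists, even adjusted over the list alone. The 4 genes of flavonoid and anthocyanin synthesis had positive changes with a median of 0.77, and UGT78D2 had a change of 0.64. Values of the members with the smallest p were -0.22 for PRK of the Calvin cycle, -0.55 for SAG101 of salicylic acid defence, 0.34 for GID1A of gibberellin, 0.21 for Fes1A of heat shock, -1.51 for STZ of reactive oxygen response and 0.47 for NDB2 of mitochondrial retrograde response. STZ was at -2.58 without wild type replicate 3, where it passed the threshold, and at -0.73 without wild type replicate 2. Values were -0.61 for the clock gene GI, -0.40 for the DNA demethylase gene DME, 0.35 for AUR1 of the cell cycle, 0.24 for BCAT4 of aliphatic glucosinolates and 0.061 for PYE of the iron list. Among markers of other tissues, mean log2 values in wild type and epiF3 were 4.16 and 4.17 for PYK10 of roots, 2.29 and 2.52 for EXPA7 of root hairs, and 2.23 and 2.33 for AMS of anthers. Lists of seed markers, ethylene, abscisic acid, sugar starvation and phosphate starvation had no measured member.

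**Figure D4:**
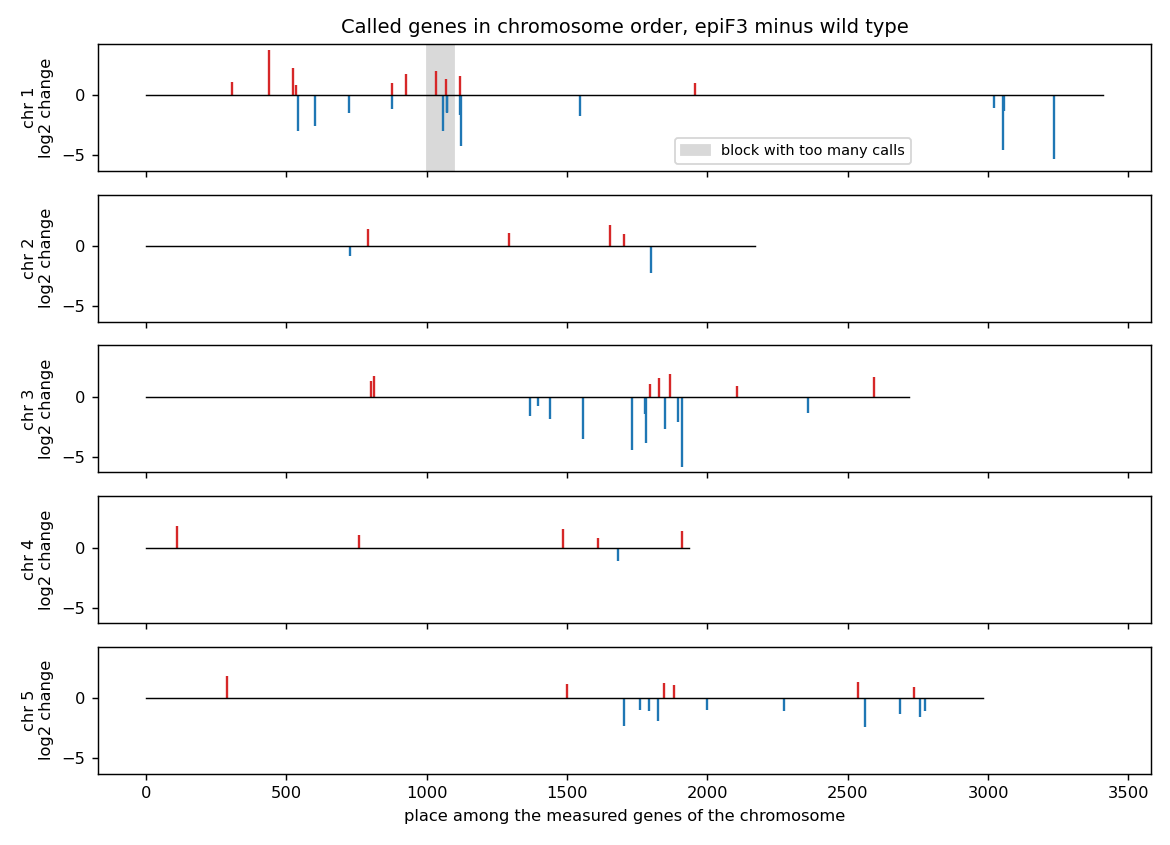
Genes past the threshold in their order along chromosomes 1 to 5, with the place among measured genes on the x axis and the log2 change, epiF3 minus wild type, on the y axis (red, rises; blue, falls). The shaded block on chromosome 1 is the 1 of 135 blocks of 100 genes whose number of calls, counted 1 by 1, passed the threshold. It holds 5 calls, some of them at adjacent places.

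The called genes lay closer together on the chromosomes than shuffled calls did, an analysis chosen after seeing the data. Of 70 called genes, 15 had another within 10 measured genes, against a mean of 7.4 with shuffled calls (permutation p = 0.0268). With called genes 1 or 2 places apart joined into 1 place, 17 of 64 places had another 3 to 20 genes away, against a mean of 12.5 (permutation p = 0.171). Of 135 blocks of 100 neighbouring genes, 1 passed the threshold with calls counted 1 by 1, from AT1G21830 to AT1G23530 in TAIR10.1 order. It held 5 calls against 0.53 expected (hypergeometric test, adjusted p = 0.0248). In that block AT1G22550 (2.02) and AT1G23120 (1.38) rose, and AT1G22890 (-2.97), AT1G23130 (-1.44) and AT1G23140 (-1.43) fell. AT1G23120, AT1G23130 and AT1G23140 lie at adjacent places. Blocks with 3 calls did not pass (adjusted p = 0.239 in the hypergeometric test), so the result rests on counting these neighbours separately. The blocks from AT3G43140 to AT3G45090 and from AT3G45100 to AT3G47080 held 4 calls each and did not pass (adjusted p = 0.0869).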

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

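The tests of epiF3 replicate 3 and the count over other splits of the arrays were chosen after the results were seen. Hybridization controls, which the comparison of plant genes does not use, averaged 2.91 log2 units more on epiF3 replicate 3 than in wild type, above every control array, and all 18 probe sets were highest there. Without this array 62 probe sets passed the threshold in limma, of which 52 were among the 136, so not all calls need it. Both fits share the other 5 arrays. In 20 simulated runs of the same form without any change at most 2 passed. These runs drew noise separately for each probe set, without deviations shared across an array. They cannot say how many calls such deviations would give. In the fit with array weights, fixed before the data were examined, epiF3 replicate 3 had the lowest weight (0.305, against 0.712 to 1.856). With its share thus reduced, 208 probe sets were higher and 241 lower, among them all 61 and all 75 of the main fit. The weighted fit still includes epiF3 replicate 3, so how much of the group difference comes from this array is not settled. Less labelled plant RNA relative to control RNA on that array remains a candidate explanation of the high controls: its plant probe sets had a 10th percentile of 2.12, against 1.93 to 1.99 on the other 5 arrays, and a smaller spread (SD 2.16, against 2.23 to 2.27). The same values would follow from other faults of that hybridization, and no biological explanation was tested.

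The real split gave 136 calls and the highest of the other 9 splits of the 6 arrays gave 0 in limma, with up to 1237 probe sets at an unadjusted p under 0.05 against 2476 for the real one. As 1 of 10 splits, the real one cannot reach a share under 0.05, so the splits are too few for that test.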

How the results depend on the processing

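The hybridization control covariate and the fit without the chromosome block were chosen after seeing the data. The covariate partly overlaps with the group, so calls lost with it can reflect lower precision alone. Against 61 probe sets higher and 75 lower, the counts were 0 and 2 with no moderation, 208 and 241 with array weights, 9 and 24 at a threshold of 0.01, and 6 and 18 with the hybridization control covariate. Leaving out 1 array gave 11 to 115 higher and 22 to 287 lower. Without moderation the spread of each probe set rests on its own 6 values, and the other causes were not tested. With the replicate number as a block the counts were 26 and 48. Same-numbered arrays did not deviate together (correlations of -0.0775, -0.0424 and -0.0453, against -0.0354 to 0.0912 for differently numbered arrays). No strong pairing by number was seen, but this cannot exclude that same-numbered samples were handled together. Without the chromosome block the counts were 57 and 68, and under the other settings they stayed within 1.5 times.

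The chlorophyll synthesis list lost its call with the hybridization control covariate (median -0.142), an estimated correlation (-0.330, adjusted p = 0.873) and fry (-0.330, adjusted p = 0.392). Its adjusted p ran from 0.000935 to 0.873. The plastid list lost its call under cyclic loess (-0.101), quantile normalization (-0.083), without the dimmest 40% (-0.098), without cross-hybridising probe sets (-0.093), with an estimated correlation (-0.093) and with fry (-0.093). Its median turned to 0.018 with the covariate, and it was -0.135 to -0.027 with 1 array left out. The causes were not tested. The 25 named genes past the threshold kept their direction. Of those not past it, PRK (0.016 without wild type replicate 1), PYE (-0.040 without wild type replicate 3) and AMS (-0.001 after quantile normalization) changed sign, and JMT, WRKY53 and STZ passed without wild type replicate 3 (2.46, -3.95 and -2.58), as did JMT (2.23) and psbC (0.57) with array weights. Leaving out 1 array moved 14 of these 25 by over 1.5 times, and 0 of the 25 past the threshold. Of the 25, 23 lost their call with no moderation, 16 with the covariate and 13 without epiF3 replicate 2. Robust and absent moderation give no camera value. Signal near the floor limits falls.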

Other observations

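The tests in this part were chosen after the data or the pattern they bear on had been seen. For the spread and the median of the genes not called in the chromosome block, what each outcome would mean was written before these values were computed. Among the 70 called genes, 7 carry a symbol of their own, 4 that rose and 3 that fell. Besides QQS, HTB11 and EXPA8, these were CYTC6A, a cytochrome c6A gene (1.3), ASPGB1, an asparaginase gene (1.33), the carboxypeptidase-like gene scpl48 (1.06) and GTR2, a glucosinolate transporter gene (0.91), chosen after their values were seen. None of 36 gene families sharing the letters of a symbol passed camera (lowest adjusted p 0.293, with 4 families at an unadjusted p under 0.05).

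Some transcripts differed widely among the wild-type arrays, and the genes given here were chosen after their values were seen. ORA47 had log2 values of 8.14, 8.68 and 4.77 on wild type replicates 1 to 3 and of 4.54, 5.50 and 4.78 on the epiF3 arrays. STZ had 8.23, 9.19 and 5.49 in wild type, and WRKY53 had 7.10, 8.06 and 4.51. Of the 100 most variable probe sets in wild type, 77 were highest on replicate 2 and 85 were lowest on replicate 3. AT5G62350 stood at 2.1 on wild type replicate 2 and at 9.31 and 10.4 on the other wild-type arrays.

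In the second look described next, called genes lay closer together on the chromosomes than shuffled calls. Its permutation p of 0.0001 to 0.0006 lie under 0.05 divided by the 9 gene order tests made (0.00556). The permutation p of 0.0268 within 10 genes and the chromosome block's adjusted p of 0.0248 (hypergeometric test) do not. The second look was chosen after the places of the calls had been seen, which that division does not cover. It also counted neighbouring calls 1 by 1, so its p argue against chance placement only with these limits. Tandem copies that share probes stay open: 21 called genes had another 3 to 20 places apart (mean 12.6 with shuffled calls, permutation p = 0.0390), but with neighbours joined the p was 0.1708. These tests use distance alone and do not look at shared probes. Of called genes 1 or 2 places apart, AT1G19450 and AT1G19485, and AT1G23830 and AT1G23850, moved in opposite directions. So did AT1G23120 against AT1G23130 and AT1G23140. The latter pair moved alike, as did AT1G73490 and AT1G73530, and AT3G44610 and AT3G44630. A segment shifted one way as a whole is argued against by the genes not called in the block, whose median change was 0.0391, within the range of random runs (-0.0239 to 0.122). A segment that differs in sequence from the arrays' reference strain may widen the spread of its other genes, and that spread (0.774) exceeded 94.5% of random runs, short of the 95% set before it was computed. Weaker binding to probes would favour falls, and the block held 3 falls and 2 rises against 35 falls and 30 rises elsewhere (Fisher's exact p = 1), too few to tell these explanations and a biological difference of the line apart.

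A second look at gene order was made, after the places of the calls had been seen, because the blocks had given only 1 past the threshold and their borders divide neighbouring calls, so its values are not independent of that first result. The most calls in any run of 200 neighbouring genes was 9, against a mean of 4.94 with shuffled calls (permutation p = 0.0006), and runs of 100 and 300 genes gave p of 0.0001, the smallest that 10000 shuffles can give, and 0.0002. Runs picked for their many calls, each with a called gene at both ends, were then described, so their counts against the genome average are no test. The runs lay between AT1G19450 and AT1G23960 (11 calls, 1.32 expected) and between AT3G43740 and AT3G47250 (9 calls, 0.96 expected). There were 5 rises and 6 falls in the former and 3 rises and 6 falls in the latter. The former held 3 of the 12 largest named rises and 2 of the 12 largest named falls, and the latter 1 and 4. In this second form the genes not called had a spread above 98.3% of random runs, where the blocks gave 94.5%. The forms differ in regions and in number of genes (100 against 430), and the question of sequence differences stays open.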
